A study of Aspergillus ruber with 4 samples.

How the data were processed

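The series holds 4 dual-colour Agilent arrays of Eurotium rubrum mycelium. Per the labels, cultures started for 3 days at 30% DSW were grown for 7 days at 27 °C in GY medium with 5%, 30% or 50% DSW, and 200 ng of RNA went into each labelling. Per the labels, replicates came from separate cultures. On the arrays of replicate 1 the Cy5 channel holds RNA labelled 30% DSW and the Cy3 channel RNA labelled 5% or 50% DSW, and on the arrays of replicate 2 the dyes are the other way round. All 4 arrays lie on 1 slide, so no batch could be tested. Groups, comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined.

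The deposited scanner tables were made with Feature Extraction 9.5.3.1, per the file headers. Per the file headers they give, for each spot and dye, the mean signal and the median local background as linear intensity before any correction. The processed signal is an intensity that the scanner software background-subtracted and normalized between dyes, per the file headers. The log10 ratio of red over green in the deposited tables was not used. The authors also deposited a value table on the log2 scale. Its columns correlated with the oriented ratios of their own arrays at r = 0.955 to 0.969, with slopes of 1.21 to 1.31, and their direction follows the dye labels. The medians of its columns were −0.019 and −0.038 for the 5% arrays of replicates 1 and 2, and −0.044 and 0.037 for the 50% arrays. Its background correction and normalization are not given in the sources used here. The submitters' processing notes name limma without a version.

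Background was corrected on the mean and local background signals with limma's normexp method (offset 50), control spots had weight 0 in the loess normalization within each array, and control spots were then left out. Over all probes, the median signal over local background in the channels labelled 5% or 50% DSW was 13.2 to 22.8, below that offset. Ratios of dim genes are therefore drawn toward 0. Spots marked as outliers by the scanner software were left out, 24 and 3 on the 5% arrays of replicates 1 and 2 and 7 and 89 on the 50% arrays. Probes well above background in at least 2 of the 8 array channels were kept, 24691 of 39437, and the probes of a gene were averaged, which gave 8420 genes. Each log2 ratio was turned to the channel labelled 5% or 50% DSW over the channel labelled 30% DSW. Spike-in spots were near background (1 to 12 of 320 well above it per channel) and were not used. Genes not well above background on either array in the channel labelled 50% DSW made up 14 of the genes called there, and their ratios are bounds.

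The probes carry gene model names of the Eurhe1 assembly, 10067 models, 9472 of them with 4 probes of 60 nt, and 53 probe sequences are shared between models. The reference table of the same assembly (Aspergillus ruber) was used for names and for which genes are neighbours. The strain label of the samples differs from the strain of that assembly, and the link of the arrays to it rests on the model names. Neighbours follow the table's order, and a fall in start coordinate was taken as the beginning of another sequence. A boundary without such a fall would be missed. Numbers in the model names matched the reference locus tags at a constant offset of 178 for 10040 models, and 27 were not matched. The next best of 200000 offsets each way matched 1285. At that offset, 95.39% of 1909 pairs of neighbours in the reference whose model names carry a scaffold number had the same number, against at most 3.46% in 100 shuffles. For 5 conserved proteins with sequences taken from general knowledge, the translated probes of the model so named shared more words of 6 residues with the protein than those of any other gene. All gene names rest on this offset. A symbol was found for 693 models, of which 663 were tested.

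The main test was limma's lmFit and eBayes on the log2 ratios of all 4 arrays with a coefficient for each salinity, which leaves 2 residual degrees of freedom per gene. The difference of the coefficients tested 50% against 5% DSW. P-values were two-sided, adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The alternatives fixed beforehand were no background subtraction, the scanner software's processed signals, median centring, scaling between arrays, no filter or a filter at 4 channels, the brightest probe, the replicate number as a block, the 2 arrays of a comparison alone, trended and robust eBayes, a 2-fold minimum, the authors' value table and leaving out each array. A filter at all 8 channels, and all settings within the fit of 2 arrays, were chosen after seeing the data. P-values rest on the spread between the 2 arrays of a group, pooled over both salinities in the fit of all 4 arrays. The 2 arrays of a group hold separate cultures, per the labels, and have opposite dye orientations. Their spread therefore mixes differences between the samples of either channel with dye effects, and these cannot be separated.

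On simulated data with independent noise at limma's moderated SD of each gene, for 50% against 30% DSW and 8420 genes, the fit of all 4 arrays recovered 72% of 200 genes changed 2-fold, 97.5% of those changed 4-fold and 98.5% of those changed 8-fold. Of its 157 calls at 2-fold, 13 were unchanged genes. The fit of 2 arrays recovered 99% at 2-fold, and 52 of its 250 calls were unchanged genes. The simulation left out dye effects and correlation between genes, and moderated SDs vary less between genes than measured ones. These shares therefore do not carry over to the real arrays. In the real fit of all 4 arrays 0 genes passed at 50% DSW, though 380 had a mean at least 2-fold higher and 93 lower.

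Gene lists came from 2 sources. Keyword lists fixed before the data were examined needed product names, and the reference table gives symbols only, so 1 of them reached the minimum of 5 measured genes (heat-shock symbols). Lists of symbols for the same and related functions were then drawn up from textbook knowledge, after the files were opened and before any gene's value was looked at. Together 32 lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the lists of a comparison. With an estimated correlation camera uses the residual degrees of freedom, 2 here, so the loss of calls was close to fixed in advance. Such a loss does not show that the genes of a list correlate. For autophagy at 50% against 5% DSW, camera's p went from 0.0145 to 0.129 with an estimated correlation of −0.038. Aquaporin, hydrophobin and glycerol-3-phosphate dehydrogenase genes, which the rule for named genes included, carry no symbol here and are not analysed here.

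The rule for named genes took, per comparison with 30% DSW, the 8 largest rises and 8 largest falls among genes with symbols that passed the threshold with the same sign on both arrays, and up to 3 rises and 3 falls per list described. For 50% against 5% DSW it took 5 of each. No gene passed in the fit of all 4 arrays. The genes for 50% DSW were therefore taken from the planned fit of 2 arrays. For 5% DSW and for 50% against 5% DSW, the genes with the largest mean ratios, of at least 2-fold with the same sign on both arrays or without overlap between groups, were named by a rule chosen after their values were seen. Errors are the SD between 2 arrays or limma's SE where stated. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, Biopython 1.88 and matplotlib 3.10.9.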

Results

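Transcript abundance was measured in mycelium of the filamentous fungus Eurotium rubrum after 7 days at 27 °C in GY medium with 5%, 30% or 50% Dead Sea water (DSW), a concentrated natural brine. Each of the 4 dual-colour Agilent arrays carried RNA labelled 30% DSW in one dye and RNA labelled 5% or 50% DSW in the other. Each comparison had 2 arrays from separate cultures, per the labels, with the dyes exchanged between replicates 1 and 2. Of 39437 probes for predicted genes, 45.2% to 62% were well above background in the channels labelled 30% DSW and 28.1% to 31.7% in the other channels. The mean background-subtracted signal of the channel labelled 30% DSW was 5.18 to 7.81 times that of the other channel of its array, and 0 gene spots were saturated. After filtering, 8420 genes were tested, of which 663 had a gene symbol. The number of arrays limits the precision of every value.

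All ratios are the channel labelled 5% or 50% DSW over the channel labelled 30% DSW, and higher and lower follow these labels. The signal patterns leave the direction open. Over 8698 probes above background in all 8 channels, the channels labelled 5% and 50% DSW correlated with r = 0.992 in replicate 1 and 0.976 in replicate 2. The channels labelled 30% DSW correlated with r = 0.598 and 0.842. If the dyes had been exchanged against the labels on all 4 arrays, every sign given here would turn. The plot of channel correlations by probe brightness shows the same order at each brightness.

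**Figure D1:**
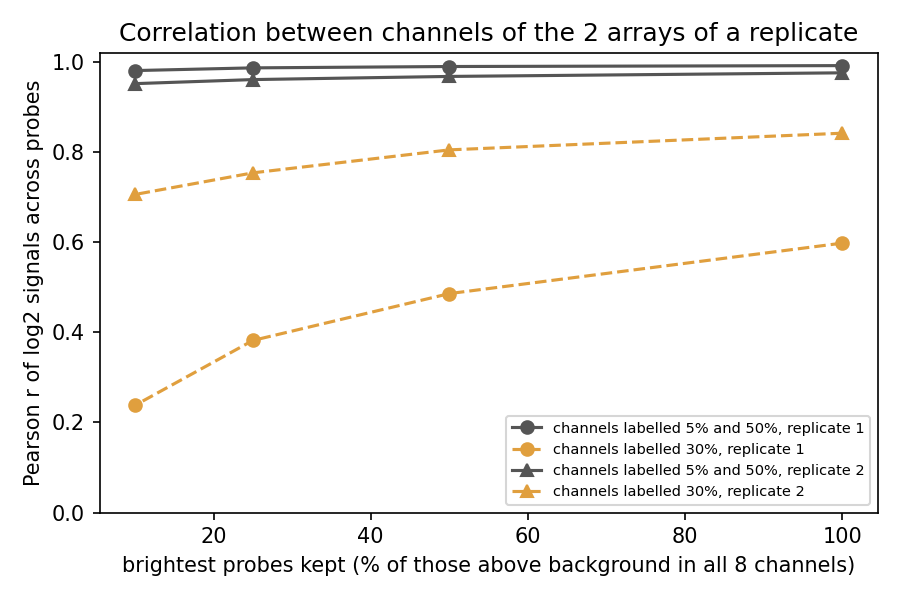
Pearson correlation of log2 signals between the 2 arrays of a replicate (vertical axis) against the share of brightest probes kept, in % of those above background in all 8 channels (horizontal axis). Probes were ranked by their mean signal in the channels labelled 5% and 50% DSW. Grey solid lines join the channels labelled 5% and 50% DSW and orange dashed lines the channels labelled 30% DSW. Among the brightest 10% the grey values were 0.981 and 0.952 and the orange values 0.238 and 0.706.

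The comparison of 50% with 30% DSW addresses the response to salinity above the reference medium. In the fit of its 2 arrays, and by the dye labels, the largest falls among genes with symbols were those of arp1, arp2 and ayg1. These adjacent genes, whose Aspergillus namesakes act in the melanin pathway of conidia, had log2 ratios of −2.55 ± 0.52, −2.23 ± 0.21 and −2.47 ± 0.70 (SD, n = 2). The pigment polyketide synthase gene pksP, looked up after its value was seen, stood at −0.46 ± 0.15 and did not pass, and the conidiation list had a median of 0.09 (camera, adjusted p = 0.748). Falls also passed the test for the endoplasmic reticulum chaperone calnexin, clxA (−1.72 ± 0.39), the cell wall glucan enzyme bgt1 (−1.61 ± 0.20), the chaperone gene hsp90 (−1.10 ± 0.12) and the ribosome biogenesis genes spb1 (−1.17 ± 0.17) and utp10 (−1.06 ± 0.03). The largest rises were those of the alpha-glucan synthase gene ags2 (2.03 ± 0.52), admB (1.69 ± 0.22), the rhamnogalacturonate lyase gene rglA (1.44 ± 0.32) and gcy1 (1.37 ± 0.53), of the glycerol dehydrogenase family. Rises also passed for the splicing factor gene cwc2 (1.37 ± 0.19, from 1 probe), the phosphoglycerate kinase gene pgkA (1.33 ± 0.17), cbpA (1.31 ± 0.33) and the cell wall protein gene ecm33 (1.30 ± 0.52). Adjusted p of these 16 genes lay between 0.021 and 0.047 in limma's fit of the 2 arrays, and between 0.15 and 0.34 in its fit of all 4 arrays, where none passed. In 0 of the 16 did a probe have the opposite sign to its gene.

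**Figure D2:**
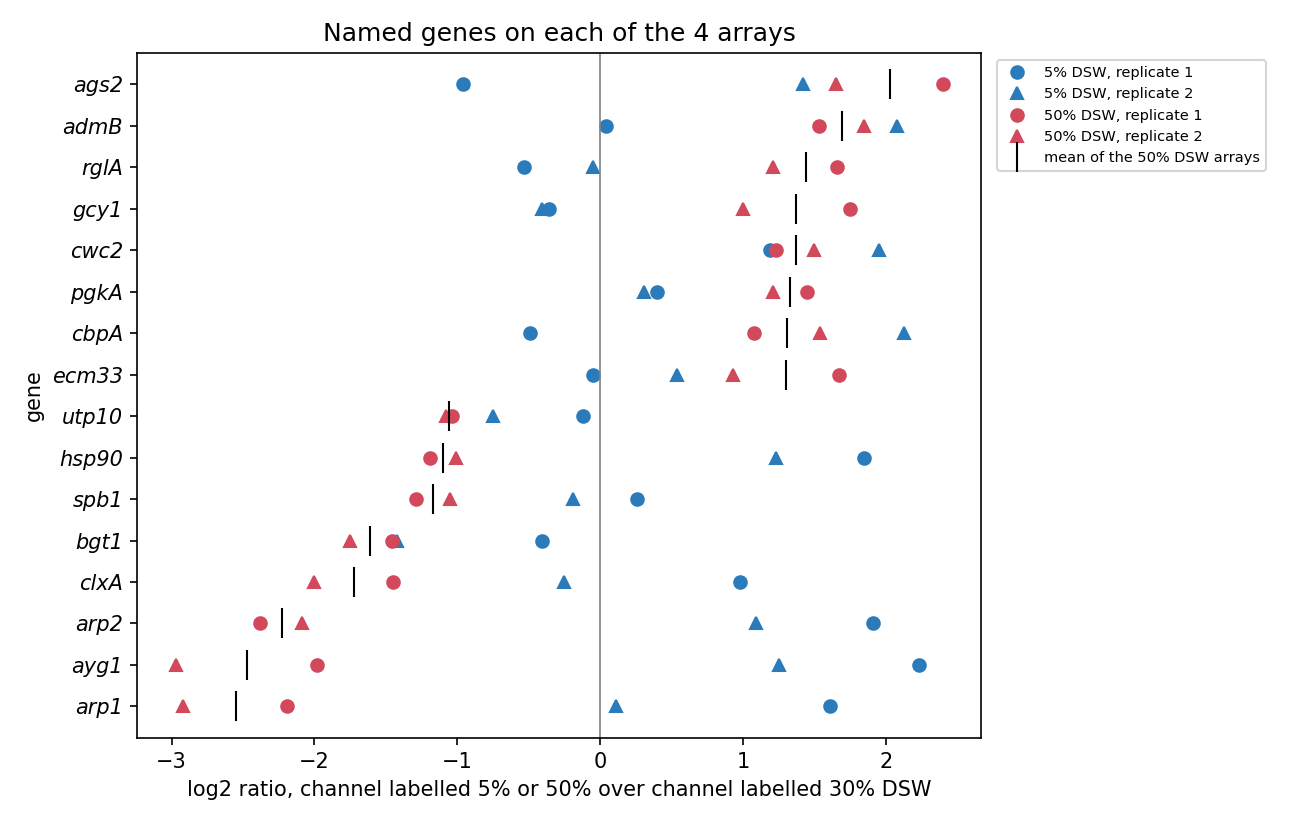
Log2 ratio of the channel labelled 5% or 50% DSW over the channel labelled 30% DSW (horizontal axis) for 16 named genes (vertical axis). Blue marks are the 5% arrays and red marks the 50% arrays, circles replicate 1 and triangles replicate 2, and the black bar is the mean of the 50% arrays, from −2.55 for arp1 to 2.03 for ags2. Under median centring in place of loess, the means of cwc2, pgkA, cbpA, gcy1 and ecm33 change sign (cwc2, gcy1 and ecm33 pass as falls in the fit of all 4 arrays), and exchanged dyes would turn every sign.

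Gene lists were tested with camera at a preset correlation between genes, and 5 of 32 lists passed at 50% DSW. The setting with an estimated correlation rests on 2 residual degrees of freedom, so a call lost there does not show that genes correlate. Glycolysis, gluconeogenesis and TCA cycle genes were higher as a group, with 10 of 11 members above 0, a median of 0.64 and adjusted p = 0.00655 (0.73 with an estimated correlation between genes), a direction that turned under median centring in place of loess. The call held in 14 of 17 alternatives. Among the 17, the 2 arrays alone and leaving out either 5% array are the same fit, here and in the other tallies at 50% DSW. In the tallies at 5% DSW, the 2 arrays alone and leaving out either 50% array are the same fit. In the fit of the 2 arrays 5 members rose, among them pgkA, the citrate synthase gene cit1 (1.23 ± 0.06) and the aconitase gene acoA (0.88 ± 0.13), while pgmA fell (−0.77 ± 0.09). Adjusted over the list alone, 8 rose and 1 fell in that fit, and 7 passed in the fit of all 4 arrays. Ribosome biogenesis genes were lower, with 24 of 25 members below 0, a median of −0.20 and adjusted p = 0.000203 by camera (0.73 with an estimated correlation), a call that held in 16 of 17 alternatives. The list's median was −0.73 with the authors' values and −1.35 with processed signals, where the median of all genes was −0.17 and −0.43. With the 2 arrays alone, 4 members fell over all genes tested and 4 adjusted over the list alone (0 and 1 in the fit of all 4 arrays), including spb1, utp10 and sik1 (−0.86 ± 0.11). In pgmA, sik1 and utr2, named here or further on, 1 probe had the opposite sign to its gene.

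Chaperone genes were lower at 50% DSW, with 11 of 13 members below 0, a median of −0.54 (−0.22 in replicate 1 and −0.51 in replicate 2) and adjusted p = 0.0243 by camera (0.73 with an estimated correlation). The call was also lost without 50% DSW replicate 2 and in 3 other alternatives, so it held in 12 of 17. In the fit of the 2 arrays 4 members fell over all genes tested and 6 adjusted over the list alone (0 and 5 in the fit of all 4 arrays): besides clxA and hsp90, falls passed for hsp88 (−0.74 ± 0.07) and hsp70 (−0.67 ± 0.15). The 5 heat-shock symbols of the keyword list, all of them also in the chaperone list, had a median of −0.67 (camera, adjusted p = 0.0107, or 0.73 with an estimated correlation), and in the fit of the 2 arrays 3 of them fell over all genes and 4 adjusted over the list alone (0 and 4 in the fit of all 4 arrays). The call held in 14 of 17 alternatives. Secondary metabolite genes were lower, with 10 of 11 below 0, a median of −0.28, a mean of −0.56 and adjusted p = 0.0221 by camera (0.73 with an estimated correlation), a call that held in 13 of 17 alternatives and was lost with processed signals, median centring and the filter at 8 channels. The list's median was −0.80 with the authors' values and −1.31 with processed signals. Of its members 1 passed in the fit of the 2 arrays, ayg1, and 1 adjusted over the list alone (0 and 3 in the fit of all 4 arrays). By fry's one-way test 0 lists passed, with a lowest adjusted p of 0.196, and by its mixed test 0.

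Several groups related to salt stress did not pass as lists at 50% DSW. The calcium transport list had 7 of 8 members above 0 (camera, adjusted p = 0.0975), and the calcium ATPase gene pmcB (0.79 ± 0.19) and the calcium channel gene midA (0.74 ± 0.18) rose in the fit of the 2 arrays, with 4 rises adjusted over the list alone. Under median centring pmcB turned to −0.12. Chitin and glucan enzymes had 18 of 24 members above 0 (camera, adjusted p = 0.107). Of these, 4 rose in the fit of the 2 arrays, among them ags2, ecm33 and utr2 (1.11 ± 0.34), and bgt1 fell, against 9 and 1 adjusted over the list alone. The proteasome list had 11 of 15 members below 0 (camera, adjusted p = 0.108), and pup3 (−0.72 ± 0.07), pre5 (−0.66 ± 0.13) and pup2 (−0.59 ± 0.06) fell in the fit of the 2 arrays. In the camera test on the fit of the 2 arrays alone, the proteasome and the chitin and glucan lists passed with adjusted p of 0.0212 and 0.0354. With an estimated correlation, tested in the fit of all 4 arrays only, camera gave both an adjusted p of 0.73. The HOG osmotic stress pathway had a median of 0.15 (camera, adjusted p = 0.172) with 0 members past limma's test in either fit, and the glycerol and trehalose list a median of −0.01 and a mean of 0.24 (camera, adjusted p = 0.521), with a rise of gcy1.

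**Figure D3:**
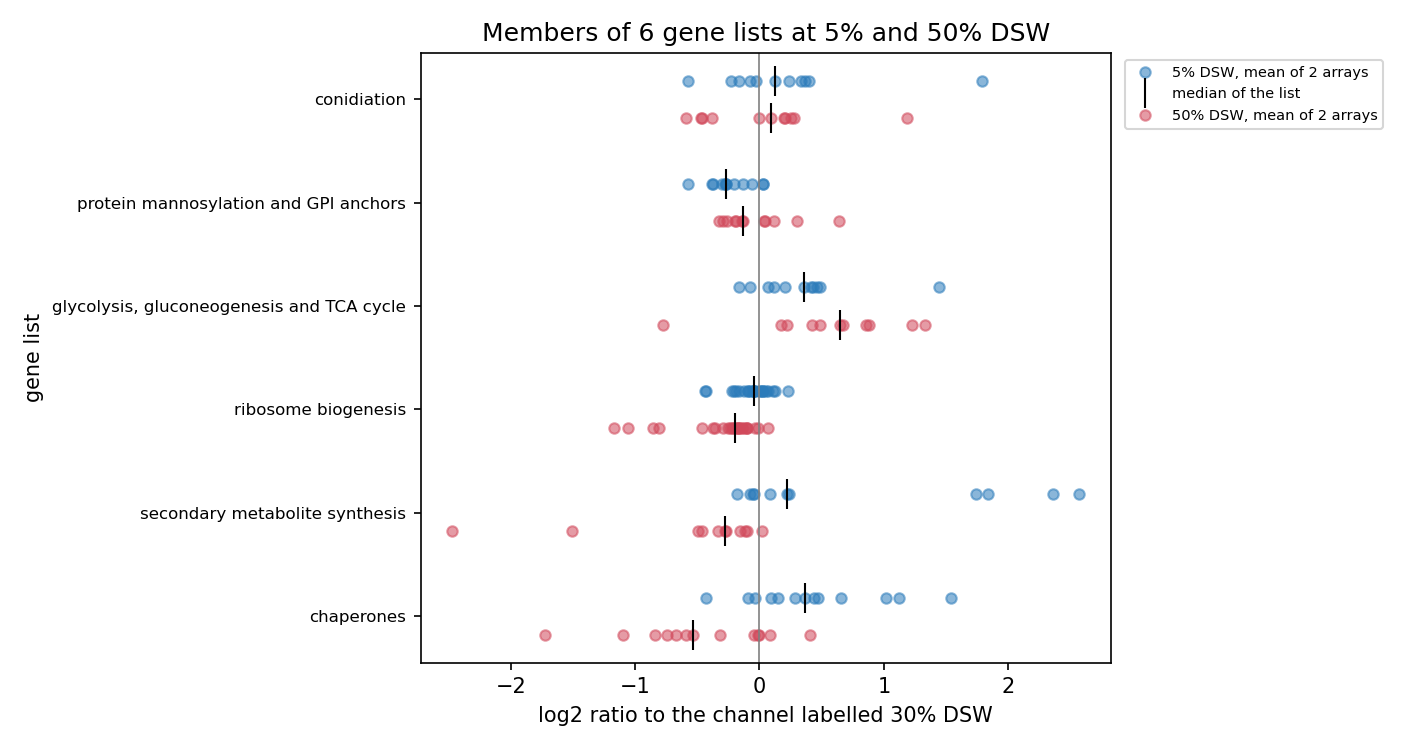
Mean log2 ratio to the channel labelled 30% DSW (horizontal axis) of each member of 6 gene lists (vertical axis), in blue for 5% DSW and red for 50% DSW, each the mean of 2 arrays, with the list's median as a black bar. The median of the chaperone list was 0.36 at 5% and −0.54 at 50% DSW. Under median centring in place of loess the chaperone direction at 5% and the glycolysis direction at 5% and 50% turn, and exchanged dyes would turn every sign.

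Over all genes, the fit of the 2 arrays at 50% DSW called 761 genes, 513 higher and 248 lower, of which 354 differed at least 2-fold. Of the 663 genes with symbols, 37 were higher and 26 lower. The fit of all 4 arrays, chosen as the main test before the data were examined, called 0 of 8420 genes with limma, against 1714 genes at an unadjusted p under 0.05 and 421 by chance, with a smallest adjusted p of 0.148. Within the fit of the 2 arrays the count was 0 with limma's trended and robust eBayes setting (2861 at an unadjusted p under 0.05) and 20 without background subtraction. Median centring in place of loess gave 155 higher and 4119 lower genes.

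The comparison of 5% with 30% DSW addresses the response to salinity below the reference medium. No gene passed the main test: limma called 0 of 8420 genes in the fit of all 4 arrays, with 987 at an unadjusted p under 0.05 and a smallest adjusted p of 0.067, and 0 in the fit of the 2 arrays, with 489 at an unadjusted p under 0.05. Without 5% DSW replicate 1, 2 genes passed, and with a term for the dye orientation, which is also the replicate number, 31 passed (30 higher, 1 lower). By the dye labels, the named genes with the highest mean ratios were nscD, for a prenyltransferase of secondary metabolism (2.57 ± 0.73, SD, n = 2), the endocrocin cluster gene encD (2.36 ± 1.74) and the glucanosyltransferase gene gel2 (1.97 ± 0.15). Then came encC of the endocrocin cluster (1.84 ± 1.29), CweA (1.79 ± 0.28), the developmental regulator gene medA (1.79 ± 0.86), hxB (1.78 ± 1.38) and the pigment gene ayg1 (1.74 ± 0.69). The lowest were aeiA (−1.34 ± 0.67), ish1 (−1.11 ± 0.58) and the sterol synthesis gene erg2 (−1.01 ± 0.98). Adjusted p of these genes lay between 0.22 and 0.43 in limma's fit of all 4 arrays. Among genes with symbols, 27 had a mean of at least 2-fold with the same sign on both arrays, 24 of them higher and 3 lower. The balance depended on the scaling: over all genes, median centring in place of loess called 4 higher and 909 lower in the fit of all 4 arrays.

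At 5% DSW 4 lists passed in camera, all without a member that passed over all genes tested; counts adjusted over the list alone are from the fit of all 4 arrays. Chaperone genes were higher, with 10 of 13 members above 0, a median of 0.36 and adjusted p = 0.00533 (0.802 with an estimated correlation), and 4 members passed adjusted over the list alone. The medians were 0.53 in replicate 1 and 0.10 in replicate 2, and the call held in 13 of 17 alternatives, lost without 5% DSW replicate 1, with median centring and with the filter at 8 channels. The keyword list of heat-shock symbols had a median of 0.47 (camera, adjusted p = 0.00128, or 0.802 with an estimated correlation), with 3 adjusted over the list alone, a call also lost with median centring, the brightest probe and without 5% DSW replicate 1; hsp90 stood at 1.54 ± 0.44 and hsp70 at 1.12 ± 0.19. Glycolysis, gluconeogenesis and TCA cycle genes had 9 of 11 members above 0 and a median of 0.36, or 0.10 in replicate 1 and 0.50 in replicate 2 (camera, adjusted p = 0.0157, or 0.802 with an estimated correlation), with 1 adjusted over the list alone. That call was kept in 9 of 17 alternatives, and lost among others with processed signals, the brightest probe, the authors' values and without 5% DSW replicate 2. Under median centring glycolysis passed as lower. The directions of these 3 lists turned under median centring in place of loess. Protein mannosylation and GPI anchor genes were lower, with 10 of 12 below 0, a median of −0.27 and adjusted p = 0.0299 by camera (0.802 with an estimated correlation), and 0 adjusted over the list alone. That call was also lost with processed signals, the authors' values and without 5% DSW replicate 1. The fry test passed 0 lists one way and 3 in its mixed test, none of them among these 4 (conidiation and peroxisome biogenesis, adjusted p = 0.0257, and secondary metabolite genes, 0.037). Without 5% DSW replicate 1, 1 list passed.

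The 5% arrays differed from each other more than the 50% arrays did. Across the 8420 genes, which are not independent replicates, the log2 ratios correlated with r = 0.25 between the 5% arrays and r = 0.75 between the 50% arrays, and the median SD between arrays was 0.182 and 0.121. The 5% array of replicate 2 correlated with the 50% arrays at r = 0.66 and 0.31, and the 5% array of replicate 1 at r = −0.13 and −0.14.

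The comparison of 50% with 5% DSW, indirect through the channels labelled 30% DSW, addresses whether the responses to high and low salinity differ. By the dye labels, the lowest values among named genes were those of the pigment genes ayg1 (−4.21 ± 0.50, SE over 4 arrays), arp2 (−3.73 ± 0.33) and arp1 (−3.42 ± 0.60), with encD at −3.87 ± 1.16 and nscD at −2.91 ± 0.50. The highest were aeiA (2.58 ± 0.55), ags2 (1.80 ± 0.88), gcy1 (1.76 ± 0.30), rglA (1.73 ± 0.27) and aspf34 (1.48 ± 0.21). None passed in limma's fit of all 4 arrays (adjusted p 0.27 to 0.48), where 0 of 8420 genes passed and 1099 had an unadjusted p under 0.05. The trended and robust eBayes setting called 38 genes. Values of the 5% and 50% arrays did not overlap for 328 of the 663 genes with symbols, or 49.5%, where 4 independent arrays would give 33.3%. The latter share leaves out the dye orientation common to same-numbered arrays, whose deviations correlated at 0.48.

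In this comparison 4 lists passed in camera, all lower at 50% than at 5% DSW. Chaperones had a median of −0.89 with 11 of 13 below 0 (camera, adjusted p = 0.000118), and the keyword list of heat-shock symbols a median of −1.06 (camera, adjusted p = 4.47e-05). With an estimated correlation both calls were lost, as were the next 2 (camera, adjusted p = 0.844 for each list). That setting rests on 2 residual degrees of freedom and could hardly keep a call. Secondary metabolite genes had a median of −0.51 and a mean of −1.35 with 10 of 11 below 0 (camera, adjusted p = 0.000674), and ribosome biogenesis genes a median of −0.17 with 24 of 25 below 0 (camera, adjusted p = 0.00467). The ribosome biogenesis call was also lost without 5% DSW replicate 1 and without 50% DSW replicate 2, and the others held in 15 of 16 alternatives. Over all genes tested 0 members passed limma's test, and adjusted over the list alone 5 chaperones, 4 heat-shock symbols, 2 secondary metabolite genes and 0 ribosome biogenesis genes passed. The fry test passed 0 lists one way and 6 in its mixed test, of the above only secondary metabolite genes (adjusted p = 0.0242). Without 5% DSW replicate 2, 7 lists passed in camera. Split by channel after loess and Aquantile normalization, a test chosen after seeing the data, the differences lay in the channels labelled 30% DSW, which should hold the same condition. Each part is a contribution to the difference of the log2 ratios. A negative part of the channels labelled 30% DSW therefore stands for a higher signal in them on the 50% arrays than on the 5% arrays. Their part had a mean of −1.13 for chaperones, −1.58 for the keyword list, −1.79 for secondary metabolite and −0.37 for ribosome biogenesis genes. The channels labelled 5% and 50% DSW contributed 0.24, 0.25, 0.45 and 0.12, of the opposite sign to the difference, so their signal was also higher on the 50% arrays.

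Across genes, the 5% and 50% responses correlated with r = 0.33 (Spearman's rho 0.23) and had the same sign for 59.1% of 8420 genes. Simulated unchanged groups with a shared reference gave r = 0.50 and 66.6%. The covariance was 0.072, against 0.023 in the simulation. Part of the observed value may come from shared 30% samples, since the labels do not say whether these were the same RNA. With the dyes as labelled that is argued against, because the channels labelled 30% DSW correlated at only 0.598 and 0.842 within a replicate. The other channels correlated at 0.992 and 0.976, so the simulated baseline would apply if the dyes had been exchanged. Within replicate 1 the correlation was −0.14 and within replicate 2 it was 0.66, and without 5% DSW replicate 2 it was −0.15. At an unadjusted p under 0.05 in limma, 235 genes were higher in both comparisons, against 63 for independent lists and 66 in simulated unchanged groups with a shared reference. Another 21 were lower in both comparisons, against 39 and 65. A further 71 genes were higher at 5% and lower at 50% DSW, against 53 and 4, and 41 were lower at 5% and higher at 50%, against 46 and 3. The independent counts leave out a shared reference and the simulated ones the effects.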

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

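All tests of explanations in this part were chosen after the result was seen. Each direction rests on the dye labels.

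The effects at 5% and 50% DSW differed by camera's test of their difference for 4 gene lists, all lower at 50%: chaperones (adjusted p = 0.000118), the keyword list of heat-shock symbols (4.47e-05), secondary metabolite genes (0.000674) and ribosome biogenesis genes (0.00467). Each was lost with an estimated correlation (camera, adjusted p = 0.844 with an estimated correlation). With 2 residual degrees of freedom in that setting, the loss was close to fixed in advance. A further 11 named genes moved one way on both 5% arrays and the opposite way on both 50% arrays. Their log2 values at 50% minus 5% DSW were −4.21 for ayg1, −3.87 for encD, −3.73 for arp2, −3.42 for arp1, −2.64 for hsp90, −1.79 for hsp70, −1.25 for trpE, 1.48 for aspf34, 1.73 for rglA, 1.76 for gcy1 and 2.58 for aeiA. None of these differences passed limma's test (adjusted p 0.27 to 0.36). Over all genes with symbols 118, or 17.8%, were opposite in this way, where 4 independent arrays would give 12.5%. Over all genes tested, signs matched for 75.1% between the 50% arrays and 56.8% between the 5% arrays. Such agreement raises the share without any link between the salinities, so no excess is shown.

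The channels labelled 30% DSW were less alike than the channels labelled 5% and 50% DSW, though the former should hold the same condition. The correlation between the channels labelled 5% and 50% DSW exceeded that between the channels labelled 30% by at least 0.134 in both replicates, as it would if the dyes had been exchanged against the labels on all 4 arrays. The channels labelled 30% of the 50% arrays correlated at 0.985 across replicates and dyes, against 0.583 to 0.842 with those of the 5% arrays, which exchanged dyes predict too, but those of the 5% arrays correlated with each other at 0.716. Background shared by the dim channels is argued against, because among the brightest 10% of probes these channels still correlated at 0.981 and 0.952. The difference grew there to at least 0.246, but that growth decides nothing. Probes were ranked by the channels labelled 5% and 50% DSW, and a narrower range of signal lowers a moderate correlation more than one near 1. Across replicates, the channels labelled 5% correlated at 0.918 and those labelled 50% at 0.914. Within a replicate, the channels labelled 5% and 50% correlated higher, at 0.992 and 0.976. Exchanged dyes with 30% RNA shared within a replicate predict this order too, but the pairs across replicates also differ in dye. With the dyes as labelled, separate 30% cultures would have to differ by the array they went on, with r = 0.598 between them in replicate 1. Such cultures stay possible, and the values do not exclude them, since the labels do not say whether the 30% RNA was shared.

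Under the main settings no gene passed in the fit of all 4 arrays. The median SD between the 5% arrays was 1.5 times that between the 50% arrays, so disagreement of the 5% arrays may account for part of this. Low signal is argued against, because the 5% arrays correlated at 0.26 over genes with probes above background in all 8 channels, against 0.25 over all genes. The 5% array of replicate 2 did not look like a 50% array throughout: genes at least 2-fold lower on the 50% arrays had a median of −0.21 there. Genes at least 2-fold higher on the 50% arrays had a median of 1.37 there and −0.01 on the other 5% array, so a mixed sample may be present and cannot be told apart from a culture that differed, in a channel left open: those labelled 5% of the 5% arrays correlated at 0.918 and those labelled 30% at 0.716, so the disagreement lay more in the latter.

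The chaperone list's median (0.36 and −0.54) and the means of arp1, arp2 and ayg1 had opposite signs at 5% and 50% DSW, as had that of their neighbour EURHEDRAFT_384085 (0.44 and −0.56) but not pksP (−0.07 and −0.46), while abr2 differed in sign between the 50% arrays (0.13 and −0.69), and at 5% none of these genes passed. A processing choice is argued against for the list's difference between 50% and 5% DSW, whose direction turned in 0 alternatives. It is not excluded for the opposite signs, which ended in 1 of 9 alternatives: under median centring the list's medians were −0.98 and −2.47. Dye bias of single genes is argued against for the list's difference, because between arrays of the same dye orientation the list's median difference was −1.15 in replicate 1 and −0.69 in replicate 2, though it lay in the channels labelled 30% DSW (a mean part of −1.13, against 0.24 in the others). A different content of spores might lower pigment genes, but the conidiation list had a median difference of −0.20 (quartiles −0.49 and 0.06, 8 of 11 below 0) and decides nothing. With the dyes as labelled, spores or a salinity response would act in the channels labelled 5% and 50% DSW. There the chaperone list's mean part was 0.24, the opposite way, which argues against both for that list's difference. The split by channel was made for lists, so for the pigment genes as a group the 2 cannot be told apart. The secondary metabolite list, which holds ayg1, had mean parts of 0.45 in the channels labelled 5% and 50% DSW and −1.79 in those labelled 30%. Samples labelled 30% DSW that differed stay open, as do exchanged dyes, under which a salinity response with every sign turned remains possible.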

How the results depend on the processing

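The filter at all 8 channels, the alternatives within the fit of 2 arrays and those for lists at 50% against 5% DSW were tests chosen after seeing the data; the others were planned. The cause was not tested unless stated. Median centring in place of loess shifted the median of all genes to −0.47 at 5% and −0.54 at 50% DSW, the processed signals to −0.37 and −0.43, the authors' value table to −0.11 and −0.17, and the filter at 8 channels to 0.08 and 0.21.

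At 5% DSW the fit of all 4 arrays called 0 genes. Calls were 65 (46 higher, 19 lower) with processed signals, 913 (4 higher, 909 lower) with median centring, 36 (31 and 5) with the authors' values, 2 with the filter at 4 channels, 3 with the filter at 8, and 0 to 2 leaving out an array (2 without 5% DSW replicate 1). At 50% DSW the same fit called 0 genes. Calls were 283 (126 and 157) with processed signals, 2710 (6 and 2704) with median centring, 202 (122 and 80) with the authors' values, 761 (513 and 248) with the 2 arrays alone, and 0 to 761 leaving out an array. The count was 761 without 5% DSW replicate 1 or 2, since what is left then estimates the spread from the 50% arrays. For 50% against 5% DSW, 0 became 7 with the authors' values and 38 with trended and robust eBayes, and leaving out any array gave 0. With an arm of 1 array, that array is assumed to vary like the others.

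In the fit of 2 arrays at 50% DSW, 761 calls became 20 without background subtraction (all 20 shared), 2134 (767 and 1367; 568 shared) with processed signals, 4274 (155 and 4119; 423 shared) with median centring, 281 without a filter, 1219 with the brightest probe, 1919 (915 and 1004; 669 shared) with the authors' values, 1280 with the filter at 8 channels, 354 with a 2-fold minimum and 0 with trended and robust eBayes, where 2861 genes had an unadjusted p under 0.05 in limma. Scaling between arrays gave 780 and the filter at 4 channels 944.

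With the replicate number as a block, which is also a term for the dye orientation, calls were 31 (30 and 1) at 5%, 0 at 50% and 0 for 50% against 5% DSW, and lists 5, 6 and 5. Deviations of same-numbered arrays correlated at 0.48, but these share the orientation, and 2 pairs cannot show pairing.

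Lists past camera's threshold at 5% DSW numbered 4, but 2 with the brightest probe, 0 with an estimated correlation and 1 to 5 leaving out an array (1 without 5% DSW replicate 1). At 50% DSW 5 became 2 with processed signals, 3 with the authors' values, 0 with an estimated correlation and 4 to 7 leaving out an array. For 50% against 5% DSW 4 became 0 with an estimated correlation and 3 to 7 leaving out an array (7 without 5% DSW replicate 2). With an estimated correlation, camera's 2 residual degrees of freedom made a count of 0 likely whatever the correlation. The correlation of the responses ranged from −0.15 (without 5% DSW replicate 2) to 0.52, against an SD of 0.57 between replicates.

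Median centring turned the 50% DSW values of pmcB to −0.12, trr1 to −0.05, cbpA to −0.22 and cit1 to −0.13, all above the shift of all genes, and of cwc2 to −1.06, pgkA to −0.79, gcy1 to −1.23, ecm33 to −1.24, acoA to −0.69 and fhpA to −1.07, below it. As falls, cwc2, gcy1, ecm33 and fhpA passed in the fit of 4 arrays (adjusted p = 0.041, 0.026, 0.022 and 0.033). No named gene passed in the main fit of 4 arrays. Of 593 values of named genes at 50% DSW under the alternatives, 455 kept the direction of the main fit and also did not pass. Another 128 kept it and passed, and the 10 above turned. At 5% DSW it was 170 and 16 of 186, and for 50% against 5% DSW 157 and 2 of 159. Passes with the 2 arrays alone or without either 5% array were fixed in advance, since the genes for 50% DSW were chosen by that fit. They make up most of the 128. Channels labelled 5% or 50% DSW had at most 31.7% of probes well above background, which limits the measurement of dim genes.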

Other observations

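The test of neighbouring genes was planned before its result was seen; the genes and runs named in this part were chosen after their values were seen. Directions follow the dye labels, and exchanged dyes would turn every sign.

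Some groups not described above held genes that passed limma's fit of the 2 arrays at 50% DSW. The oxidative stress list had 2 rises, the thioredoxin reductase gene trr1 (1.16 ± 0.02, SD, n = 2) and the flavohaemoprotein gene fhpA (1.04 ± 0.20), with camera's adjusted p = 0.46 for the list. Under median centring trr1 was −0.05 and fhpA −1.07, and fhpA passed as a fall. In the ergosterol list the squalene epoxidase gene erg1 rose (1.22 ± 0.36), with camera's adjusted p = 0.403. In the COPII secretion list sec11 (−0.76 ± 0.17) and sly1 (−0.72 ± 0.14) fell (camera, adjusted p = 0.403), in mitochondrial protein import tom70 fell (−0.69 ± 0.17; camera, adjusted p = 0.828), and in amino acid synthesis trpE fell (−0.84 ± 0.26; camera, adjusted p = 0.178). The conidiation list stood at a median of 0.12 at 5% and 0.09 at 50% DSW (camera, adjusted p = 0.497 and 0.748), with members on both sides of 0, and passed fry's mixed test at 5% DSW (adjusted p = 0.0257) and for 50% against 5% DSW (0.0457).

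Pigment genes were neighbours. In the reference order arp1, arp2 and ayg1 lie side by side, followed by EURHEDRAFT_384085, abr1 and abr2. At 50% DSW the first 3 stood at −2.55, −2.23 and −2.47, EURHEDRAFT_384085 at −0.56, and the multicopper oxidase-type pigment gene abr2 at −0.28. The ratio of abr1 is a bound, since its channel labelled 50% DSW was well above background on 0 arrays. A run of 4 unnamed neighbours (EURHEDRAFT_415649, EURHEDRAFT_415651, EURHEDRAFT_380321 and EURHEDRAFT_380322) stood at −1.08, −2.48, −1.54 and −2.03 at 50% and at 0.86, 2.06, 1.32 and 4.42 at 5% DSW. In the fit of the 2 arrays at 50% DSW, EURHEDRAFT_415651 and EURHEDRAFT_380321 passed limma's test (adjusted p = 0.028 and 0.038) and the others did not (0.065 and 0.099).

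One hypothesis was that neighbouring genes respond alike, as they may where they share regulation. Over 7127 adjacent pairs the log2 ratios correlated at 0.13 at 50% DSW, against at most 0.02 in 100 shuffled gene orders, and at 0.14 at 5% DSW, against at most 0.03. Runs of at least 3 neighbours, each at least 2-fold in the same direction, numbered 8 at 50% DSW (at most 2 in shuffled orders) and 5 at 5% DSW (at most 1). At 50% DSW the run of arp1, arp2 and ayg1 and the run from EURHEDRAFT_415649 were lower and the other runs higher. All runs at 5% DSW were higher. Shared regulation of neighbours predicts such correlation and runs, but related gene copies that share probe sequence in part would too, and that was not tested.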
